A study of Mus musculus with 9 samples.

How the data were processed

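Liver sections of 9 samples, 3 each of Adar wt/wt, wt/flox and flox/flox on an Ifih1-null, albumin-Cre background, were profiled with 10x Visium. Per the labels' protocols, frozen tissue was embedded in OCT, 3 sections of each tissue were placed on slides, and 9 libraries were pooled. Nothing in the labels says whether the 3 samples of a genotype come from separate animals, so they may be sections of 1 tissue, and p-values then measure only the spread between sections, which may be technical. The deposited files hold UMI counts per gene and spot, which Space Ranger made and Seurat then handled, per the submitters' processing notes, with versions not given in the sources used here. The files pair Ensembl identifiers with symbols, and genes are named here by symbol. Of 32285 genes, 20683 had at least 1 UMI, and 38 symbols belonged to more than 1 identifier.

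UMI counts were summed over all spots of a sample. edgeR 4.0.16 (R 4.3.3) was run with TMM factors (0.80 to 0.92 in wt/wt, 0.93 to 0.96 in wt/flox, 1.20 to 1.24 in flox/flox), filterByExpr, which kept 14034 genes and left out 18251, and the quasi-likelihood test over all 9 samples, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. The common dispersion was 0.0119 (a biological coefficient of variation of 10.9%), with 6 residual and 6.13 prior degrees of freedom. A count of 3 UMIs in a library equals 0.0447 to 0.0891 CPM on the normalised library size. Any 2 samples of a genotype differed by more than sampling noise (chi-square over degrees of freedom 4.92 to 117), so all 9 were kept as separate samples. Xist was found in each sample (1690 to 4264 UMIs).

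The named genes are Adar, Ifih1, Grn and Egfr, and for each comparison the 12 largest and 12 smallest log2 fold changes among genes with adjusted p below 0.05, at least 5 CPM in the higher genotype and no overlap between the samples of the 2 genotypes. Each list adds up to 4 members with the smallest adjusted p, the zone test adds 6 genes per direction, and predicted genes are counted but not named. Some genes that the rule picks are not reported here. Genes outside this rule were chosen after their values were seen: Ngp, Ltf, Camp and Ccl8, given for their low counts. The rule, the tests, the alternatives and 39 gene lists were fixed before the data were examined. The lists were type I interferon-stimulated genes, interferon-gamma-induced GTPases and chemokines, MHC class I and class II presentation, cell death effectors, and markers of Kupffer cells, all macrophages, monocyte-derived and lipid-associated macrophages, T and NK cells, B and plasma cells, neutrophils, sinusoidal endothelium, quiescent stellate cells and cholangiocytes. They also covered chemokines, extracellular matrix, oncofetal, proliferation, p53, ER stress, acute-phase, NF-kB, progranulin and EGFR axis, lysosomal, pericentral, periportal, secretory, bile acid, xenobiotic, fatty acid oxidation, lipogenesis, cholesterol, urea cycle, complement, mitochondrially encoded, erythroid, immediate-early, clock, and heat shock and hypoxia genes. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and with an estimated one, adjusted over the 39 lists of a comparison.

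Spots of each sample were ranked by the log ratio of pericentral (Glul, Cyp2e1, Cyp1a2, Oat, Rgn, Slc1a2) to periportal UMIs (Cyp2f2, Hal, Sds, Hsd17b13, Hsd17b6, Gls2), and UMIs were summed over the top and bottom tertile. The 12 anchors were left out of the results, and edgeR tested the interaction of zone and genotype with the sample as a block over 13053 genes. In the spot measures, each spot was thinned to 3000 UMIs, which left out 18 to 114 spots per sample (0.429 to 3.10%), and tested by exact permutation.

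The alternatives were DESeq2 1.42.0, RLE factors, library size alone, no filter, a mean of at least 5 CPM, limma-voom, and a replicate block. Others were a block of the number in the file names, only the 2 genotypes compared, each sample left out in turn, spots of at least 3000 UMIs, 2736 spots per sample, totals thinned to 28.159 M UMIs, and mitochondrially encoded and the 20 most abundant genes left out. For lists they were fry, which tests whether the genes of a list move on balance one way, a block and samples left out, for zones narrower zones, a 4-gene index and thinning, and for spots thinning to 5000 or 1500 UMIs. Pairs of a wt/wt and a wt/flox sample with the same replicate number had residual correlations of 0.118, 0.196 and 0.259. Those with unlike numbers had -0.211 to 0.088. Such values alone do not establish a pairing. The pairs with the same replicate number also share the number in the file names, which 1 flox/flox sample shares with the second pair and 2 with the last pair, so this block is not balanced. The residual correlations of these flox/flox samples with their wt/wt samples were 0.350, 0.121 and 0.343, and with their wt/flox samples 0.143, 0.016 and 0.181. On simulated counts for 13527 genes, 8, 54, 92 and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold (50 each) were called, with 8 false calls among 13327 unchanged genes and none when no gene changed. The simulated list test called the 1 shifted list and none of the other 38, and the zone test called 48, 60, 88 and 100% of changed genes, with 11 false calls among 12214. Genes were simulated independently of each other, so the list test was not checked for false calls among correlated genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for spot measures and figures.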

Results

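The series profiled frozen liver tissue of 8-week-old female C57BL/6 mice with 10x Visium, which captures polyadenylated RNA from a 10 µm section on spots that each carry their own barcode. All 9 samples lacked Ifih1, which encodes the double-stranded RNA sensor MDA5, and carried Cre recombinase under the albumin promoter, which acts in hepatocytes. They differed in Adar, which encodes the RNA-editing enzyme ADAR1: both alleles unfloxed (wt/wt), 1 floxed allele (wt/flox) or 2 floxed alleles (flox/flox), with 3 samples of each. The files held 30193 spots, each a small tissue region that can hold several cells. There were 4198, 4538 and 4579 spots in the wt/wt samples, 2737, 2928 and 2868 in wt/flox, and 2868, 2736 and 2741 in flox/flox. Unique molecular identifiers (UMIs), in M (mega), summed to 69.4, 75.9 and 51.0 M per wt/wt sample, 39.7, 38.4 and 35.1 M per wt/flox sample, and 33.4, 28.2 and 33.1 M per flox/flox sample. The median spot held 14220.2 ± 2895 UMIs in wt/wt, 12190 ± 1371 in wt/flox and 9596 ± 1018 in flox/flox (mean ± SD, n = 3). Albumin transcripts made up 12.8 ± 0.520% of UMIs in wt/wt, 11.2 ± 0.519% in wt/flox and 7.56 ± 0.157% in flox/flox, and the 20 most abundant genes 35.3, 32.2 and 26.4%. The first principal component of the summed profiles held 66.8% of the variance and placed the flox/flox samples between 51.5 and 60.0 and the other 6 below 0. wt/wt replicate 3 stood apart on the second component (13.9% of the variance), at -39.9 against -5.74 to -4.62 for the other wt/wt samples, and 5.66% of its UMIs came from ribosomal protein genes against a wt/wt mean of 4.30%. Levels are given below as UMIs in every M of the library (CPM) on the normalised library size, as mean ± SD over the 3 samples of a genotype, and errors of log2 fold changes are standard errors (SE).

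Adar transcripts rose with the number of floxed alleles. Adar had 941, 980 and 670 UMIs in the wt/wt samples, 779, 709 and 718 in wt/flox and 1377, 1094 and 1304 in flox/flox. The level was 15.2 ± 0.983 CPM in wt/wt, 20.7 ± 0.741 in wt/flox and 32.6 ± 0.537 in flox/flox. Flox/flox exceeded wt/wt by a log2 fold change of 1.10, SE 0.08 (edgeR adjusted p = 4.47e-07), wt/flox exceeded wt/wt by 0.45, SE 0.08 (adjusted p = 0.00404) and flox/flox exceeded wt/flox by 0.65, SE 0.08 (adjusted p = 4.95e-05). The labels do not say which exons are floxed, and the assay tags the 3' end of transcripts, which a shortened transcript would keep, so these levels do not check the deletion. Ifih1 had 1 UMI over the 9 samples and checks nothing here, since no sample had an intact Ifih1 gene. Of the pair named in the series title, Egfr (epidermal growth factor receptor) was at 206 ± 16.7 CPM in wt/wt, 208 ± 15.6 in wt/flox and 136 ± 12.5 in flox/flox. It fell in flox/flox against wt/wt (log2 fold change -0.60, SE 0.10, adjusted p = 3.20e-04) and against wt/flox (-0.61, SE 0.10, adjusted p = 4.40e-04), and its log2 fold change in wt/flox against wt/wt was 0.01, SE 0.10 (adjusted p = 0.962). Scaled to library size alone, the falls of Egfr were -0.12 and -0.23 and did not pass the test (adjusted p = 0.376 and 0.0930). Grn, which encodes progranulin (PGRN), was at 304 ± 13.5, 364 ± 41.2 and 352 ± 15.1 CPM, and none of its 3 comparisons passed the test (adjusted p = 0.0884 for flox/flox against wt/wt, 0.105 for wt/flox against wt/wt and 0.736 for flox/flox against wt/flox). The log2 fold change of Grn in flox/flox against wt/wt was 0.21, SE 0.10, and with library size alone it was 0.70 (adjusted p = 9.1e-05, the lowest over 22 alternatives, the highest being 0.230). With the number in the file names as a block, Grn passed in flox/flox against wt/wt (log2 fold change 0.23, adjusted p = 0.0425) and in wt/flox against wt/wt (0.25, adjusted p = 0.0419, with 0.0352 to 0.365 over 22 alternatives). The call on Grn thus depends on the settings, and it passed in 4, 2 and 1 of 22 alternatives for the 3 comparisons in the order above.

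The comparison of flox/flox with wt/wt set 2 floxed Adar alleles against none, with hepatocyte Cre on the Ifih1-null background. The samples of a genotype may be sections of 1 tissue. A difference between animals therefore cannot be told apart from the floxed alleles, here or in the 2 comparisons below. Transcripts that were scarce in wt/wt liver became readily detected. Gsta1, a glutathione S-transferase, rose from 0.101 ± 0.0242 to 27.0 ± 7.40 CPM (log2 fold change 7.97, SE 0.30, adjusted p = 2.95e-09), a ratio of 256 (95% exact interval 162 to 432, covering counting error only). Ratios of summed UMIs here and below are divided by the ratio of the normalised library sizes, so they differ from the ratio of the counts themselves. Ubd, an interferon- and TNF-induced ubiquitin-like modifier, rose from 0.123 ± 0.0335 to 15.7 ± 3.06 CPM, a scaled ratio of 128 (83.4 to 207). The calcium-binding protein gene Cib3 rose from 1.70 ± 0.265 to 140.4 ± 18.8 CPM (log2 fold change 6.38, SE 0.15, adjusted p = 1.59e-10). Slpi, a secreted protease inhibitor, rose from 0.558 ± 0.0214 to 35.5 ± 8.52 CPM, and the trypsin inhibitor gene Spink1 from 0.237 ± 0.0537 to 14.1 ± 2.11. Timp1, an inhibitor of matrix metalloproteinases, rose from 0.297 ± 0.0398 to 11.1 ± 3.00 CPM, and Col1a1, the main chain of type I collagen, from 2.46 ± 0.314 to 61.8 ± 8.03. Gpx2 (6.30, SE 0.37), Tff3 (4.96, SE 0.15), Ly6d (4.92, SE 0.19), Gstm3 (4.51, SE 0.18) and Cbr3 (4.18, SE 0.32) were the other genes among the 12 with the largest rise on the log2 scale, and the Gpx2 value was 7.03 without wt/wt replicate 1. In the opposite direction, Cyp2a22, a cytochrome P450, fell from 26.0 ± 7.38 to 0.173 ± 0.0470 CPM (20 UMIs in 3 flox/flox libraries, against 4271 in wt/wt, a scaled ratio of 144 with an exact interval of 92.9 to 236). Serpina1e, an alpha-1-antitrypsin paralog, fell from 1498 ± 123 to 89.5 ± 7.27 CPM (log2 fold change -4.07, SE 0.14, adjusted p = 1.99e-09), Cyp4a14, a fatty acid omega-hydroxylase, from 553 ± 104 to 53.3 ± 8.24 and Cyp3a44 from 362 ± 42.4 to 41.0 ± 6.13. The retinoic acid hydroxylase gene Cyp26b1 (-3.64, SE 0.21), the steroid enzyme gene Hsd3b5 (-3.50, SE 0.17) and the sulfotransferase gene Sult3a1 (-3.47, SE 0.19) also fell. The ER-associated degradation gene Derl3 (-3.44, SE 0.13), the major urinary protein genes Mup11 (-4.90, SE 0.31) and Mup16 (-3.09, SE 0.44), Dct (-3.70, SE 0.11) and Babam2 (-3.28, SE 0.17) completed the 12 largest falls.

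Interferon-response transcripts rose together. Of 39 type I interferon-stimulated genes tested, 38 rose, and 38 when adjusted over the list alone. The interferon-stimulated gene median was 1.65 (camera adjusted p = 1.31e-17, adjusted p = 0.00168 with an estimated correlation). Ifi44 rose from 3.67 ± 0.356 to 34.6 ± 1.69 CPM, Oasl2, an oligoadenylate synthetase-like protein, from 2.85 ± 0.218 to 24.0 ± 0.461, Ifit1, which binds foreign RNA caps, from 8.19 ± 1.24 to 54.5 ± 3.44, and the transcription factor gene Irf7 from 24.4 ± 3.03 to 151 ± 14.6. Among 18 interferon-gamma-induced GTPases and chemokines, 14 rose (14 adjusted over the list alone), with the guanylate-binding protein gene Gbp3 at 4.96 ± 0.171 and 18.6 ± 1.04 CPM and Gbp2 at 3.26 ± 0.355 and 8.52 ± 0.622. The list passed the camera test (median log2 fold change 0.95, adjusted p = 1.23e-05), with adjusted p = 0.0642 with an estimated correlation. MHC class I presentation genes rose at 14 of 19 members (15 adjusted over the list alone), among them H2-Q7 (73.1 ± 3.49 to 168 ± 2.81 CPM) and the immunoproteasome subunit gene Psmb8 (36.5 ± 3.70 to 82.8 ± 8.37). The class I median was 0.63 (camera adjusted p = 5.14e-05, adjusted p = 0.0332 with an estimated correlation). All 7 tested MHC class II genes rose (7 adjusted over the list alone), H2-Aa from 26.5 ± 0.871 to 94.2 ± 15.3 CPM and H2-Eb1 from 17.9 ± 2.04 to 81.9 ± 16.4. The class II median was 1.83 (camera adjusted p = 6.43e-06, adjusted p = 0.116 with an estimated correlation). NF-kB and TNF response genes rose at 11 of 14 and fell at 1 (the same counts adjusted over the list alone), the adhesion molecule genes Vcam1 (16.7 ± 0.996 to 47.8 ± 2.68 CPM) and Icam1 (11.2 ± 0.133 to 25.4 ± 1.29) among them. The NF-kB median was 1.11 (camera adjusted p = 3.40e-04, adjusted p = 0.0642 with an estimated correlation). Cell death effectors rose at 10 of 15 and fell at 1, again the same adjusted over the list alone, with the necroptosis executor gene Mlkl rising from 2.77 ± 0.218 to 8.77 ± 0.199 CPM and the death receptor gene Tnfrsf10b from 0.219 ± 0.0576 to 1.66 ± 0.116. The cell death median was 0.82 (camera adjusted p = 0.00484, adjusted p = 0.0642 with an estimated correlation).

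Markers of macrophages and other leukocytes were higher in flox/flox, by amounts that differed between lists. The monocyte-derived and lipid-associated macrophage markers rose at all 16 tested members (16 adjusted over the list alone). The monocyte-derived median was 2.78 (camera adjusted p = 1.49e-10, adjusted p = 0.0332 with an estimated correlation). Among these, Ccr2, the receptor that guides monocytes out of the marrow, rose from 0.573 ± 0.106 to 6.20 ± 0.669 CPM, the fractalkine receptor gene Cx3cr1 from 0.126 ± 0.0460 to 2.14 ± 0.110, and the tetraspanin gene Cd63 from 6.58 ± 0.467 to 43.4 ± 5.01. All 15 pan-macrophage markers rose (15 adjusted over the list alone), with Mpeg1 going from 29.8 ± 1.83 to 105 ± 2.33 CPM and C1qc from 65.5 ± 2.93 to 161 ± 19.2. The pan-macrophage median was 1.44 (camera adjusted p = 4.81e-09, adjusted p = 0.0741 with an estimated correlation). The 9 markers of Kupffer cells, the resident macrophages of the liver, also rose (9 adjusted over the list alone), Clec4f from 119.8 ± 10.2 to 286 ± 31.6 CPM and Folr2 from 16.3 ± 1.83 to 49.5 ± 4.87. The Kupffer cell median was 1.09 (camera adjusted p = 8.34e-06, adjusted p = 0.0741 with an estimated correlation). T and NK cell markers rose at all 16 tested members (16 adjusted over the list alone), including Ccl5 (4.38 ± 1.41 to 13.8 ± 1.80 CPM) and Cd8a (0.263 ± 0.0608 to 0.968 ± 0.188). The T and NK median was 1.04 (camera adjusted p = 5.02e-06, adjusted p = 0.0642 with an estimated correlation). B and plasma cell markers rose at 8 of 10 (8 adjusted over the list alone), with the immunoglobulin gene Ighm at 3.12 ± 0.442 and 9.76 ± 1.71 CPM. The B cell median was 1.35 (camera adjusted p = 4.81e-04, adjusted p = 0.0555 with an estimated correlation). Each of the 9 neutrophil markers tested rose (9 adjusted over the list alone), among them S100a8 (1.49 ± 0.297 to 11.6 ± 2.46 CPM). The neutrophil median was 2.70 (camera adjusted p = 0.00151, adjusted p = 0.218 with an estimated correlation). Of 7 erythroid and blood transcripts, 6 rose (6 adjusted over the list alone; median 1.63, camera adjusted p = 0.0532, passed by fry), with the haemoglobin gene Hba-a2 at 103 ± 37.2 and 327 ± 106 CPM. The blood content of the sections was not measured apart from such transcripts. Chemokines rose at 14 of 18 and fell at 1 (14 and 1 adjusted over the list alone), with Ccl2, which recruits monocytes, rising from 0.343 ± 0.182 to 3.84 ± 0.199 CPM and Cxcl16 from 11.8 ± 0.414 to 32.5 ± 5.41. The chemokine median was 1.39 (camera adjusted p = 4.32e-05, adjusted p = 0.0332 with an estimated correlation). The neutrophil genes Ngp, Ltf and Camp and the chemokine gene Ccl8 had 1 to 3 UMIs in all wt/wt libraries together, and setting them to the bound of their counting interval nearest to no change left the list medians at 2.70 and 1.39.

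Matrix, ductular, oncofetal and proliferation transcripts rose as well. Of 24 fibrosis and extracellular matrix genes, 23 rose (23 adjusted over the list alone), with Col3a1 at 18.6 ± 1.04 CPM in wt/wt and 190.3 ± 29.3 in flox/flox and Col1a2 at 11.02 ± 0.628 and 88.9 ± 9.63. The matrix gene median was 2.03 (camera adjusted p = 2.19e-14, adjusted p = 0.0761 with an estimated correlation). Cholangiocyte and ductular markers rose at 8 of 11 (8 adjusted over the list alone), including Spp1, which encodes osteopontin (65.4 ± 6.01 to 199 ± 17.8 CPM), and the keratin gene Krt7 (0.462 ± 0.129 to 2.71 ± 0.617). The ductular median was 1.47 (camera adjusted p = 1.14e-04, adjusted p = 0.119 with an estimated correlation). Oncofetal genes rose at 11 of 12 (12 adjusted over the list alone), with Ly6d going from 1.48 ± 0.294 to 45.8 ± 10.2 CPM and the RNA-binding protein gene Igf2bp3 from 0.114 ± 0.0232 to 1.88 ± 0.201. The oncofetal median was 1.94 (camera adjusted p = 1.20e-07, adjusted p = 0.0642 with an estimated correlation). Proliferation genes rose at 19 of 23 (19 adjusted over the list alone), Mki67, which encodes the Ki-67 antigen, from 1.38 ± 0.0528 to 5.33 ± 0.244 CPM. The proliferation median was 1.44 (camera adjusted p = 5.82e-07, adjusted p = 0.0761 with an estimated correlation). Sinusoidal endothelial markers moved less, 6 of 12 rising (6 adjusted over the list alone), with Lyve1 at 4.95 ± 0.879 and 12.5 ± 0.438 CPM. The endothelial median was 0.24 (camera adjusted p = 0.0481, adjusted p = 0.218 with an estimated correlation). This shift did not pass without wt/wt replicate 3 (median 0.18), wt/flox replicate 1, 2 or 3 (0.24 each) or flox/flox replicate 2 or 3 (0.23 and 0.22). Quiescent stellate cell markers rose at 5 of 11 and fell at 1, with the same counts adjusted over the list alone and a median of 0.39, which did not pass by camera (adjusted p = 0.216) and passed by fry. All 12 endothelial markers were higher with library size alone (median 0.73), as were 10 stellate markers, with 1 lower (median 0.87). The 1 stellate marker that fell was Lrat, which makes the retinyl esters stored by these cells (8.80 ± 1.15 to 1.84 ± 0.298 CPM, log2 fold change -2.26, SE 0.14, adjusted p = 1.30e-07), while the proteoglycan gene Dcn rose from 127 ± 4.68 to 217 ± 14.2.

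Hepatocyte metabolic and secretory genes fell. Fatty acid oxidation and PPARalpha target genes fell at 22 of 24 (23 adjusted over the list alone), with Cyp4a10 at 402 ± 43.6 and 54.5 ± 9.17 CPM, Acot1 at 49.8 ± 2.62 and 10.7 ± 0.798, and the liver fatty acid-binding protein gene Fabp1 at 7662 ± 972 and 2190.3 ± 29.2. The fatty acid oxidation median was -0.99 (camera adjusted p = 1.40e-13, adjusted p = 0.0332 with an estimated correlation). Secretory and identity genes fell at 15 of 18 (16 adjusted over the list alone), Alb from 147440.0 ± 6617 to 61837 ± 809.6 CPM (log2 fold change -1.254, SE 0.11, adjusted p = 1.77e-06) and the fibrinogen gene Fgb from 7785 ± 484 to 3292 ± 214. The secretory gene median was -0.84 (camera adjusted p = 5.32e-08, adjusted p = 0.0741 with an estimated correlation). Pericentral hepatocyte genes fell at 15 of 22 and rose at 1 (16 and 1 adjusted over the list alone), for example Cyp2c37 (571 ± 35.8 to 165 ± 26.1 CPM) and Oat (408 ± 25.2 to 172 ± 15.2). The pericentral median was -0.68 (camera adjusted p = 7.66e-06, adjusted p = 0.106 with an estimated correlation). Mitochondrially encoded transcripts fell at 11 of 13 (also 11 adjusted over the list alone), mt-Cytb from 6116 ± 1299 to 2332 ± 217 CPM. The mitochondrial median was -0.96 (camera adjusted p = 4.73e-05, adjusted p = 0.260 with an estimated correlation). All of these falls were smaller with library size alone, where 19 fatty acid oxidation genes were lower (median -0.50), 10 secretory genes lower and 2 higher (-0.34), 8 pericentral genes lower and 4 higher (-0.19), and 7 mitochondrial transcripts lower and 2 higher (-0.47). For the periportal, bile acid, urea cycle and complement lists the median changed sign with the scaling. Periportal hepatocyte genes fell at 10 of 19 and rose at 2, the same adjusted over the list alone, with the sulfotransferase gene Sult5a1 falling from 21.5 ± 1.36 to 3.65 ± 0.524 CPM. The periportal median was -0.23 (camera adjusted p = 0.0124, adjusted p = 0.308 with an estimated correlation). Bile acid synthesis and transport genes fell at 10 of 18 and rose at 2 (11 and 2 adjusted over the list alone), the organic anion transporter gene Slco1a1 falling from 86.6 ± 2.51 to 12.4 ± 1.51 CPM and Cyp8b1, which controls cholic acid synthesis, from 246 ± 45.6 to 114 ± 7.49. The bile acid median was -0.25 (camera adjusted p = 0.00392, adjusted p = 0.0642 with an estimated correlation). Urea cycle and amino acid catabolism genes fell at 11 of 18 and rose at 1 (the same adjusted over the list alone), with the tryptophan dioxygenase gene Tdo2 at 1254 ± 42.2 and 615 ± 54.7 CPM. Complement and coagulation genes fell at 12 of 21 and rose at 1 (the same adjusted over the list alone), with Cfi at 798 ± 73.1 and 487 ± 19.9. The urea cycle median was -0.39 (camera adjusted p = 0.00287, adjusted p = 0.0741 with an estimated correlation). The complement median was -0.36 (camera adjusted p = 0.00358, adjusted p = 0.335 with an estimated correlation). With library size alone the medians of these 4 lists were 0.26, 0.24, 0.12 and 0.13, with 8, 10, 6 and 8 members higher and 4, 5, 1 and 2 lower.

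Lipogenesis genes rose at 9 of 15 and fell at 2, with the same counts adjusted over the list alone. The lipogenesis median was 0.83 (camera adjusted p = 0.00596, adjusted p = 0.0642 with an estimated correlation). Scd1, which desaturates stearoyl-CoA, rose from 1252 ± 129 to 5549 ± 468 CPM (log2 fold change 2.15, SE 0.11, adjusted p = 4.03e-08), and the elongase gene Elovl6 from 28.8 ± 3.41 to 83.9 ± 9.08. Several lists held members that went both ways and did not pass the camera test, though fry, which does not compare a list with other genes, passed the xenobiotic, ER stress, p53, cholesterol and immediate-early lists. Xenobiotic metabolism genes rose at 10 and fell at 10 of 24 (the same adjusted over the list alone; median 0.03, camera adjusted p = 0.940). Among those that rose were the glutathione S-transferase genes Gsta1, Gsta2 (5.33 ± 0.328 to 35.4 ± 3.98 CPM) and Gstm3 (11.9 ± 1.32 to 271 ± 61.4) and the quinone reductase gene Nqo1. Of 26 acute-phase genes, 9 rose and 12 fell (10 and 13 adjusted over the list alone), with a median of -0.11, a mean of 0.16 and a camera direction of down (adjusted p = 0.609), while 13 were higher and 6 lower with library size alone (median 0.36). The serum amyloid gene Saa1 rose from 104 ± 15.9 to 543 ± 47.7 CPM and the iron-siderophore binder gene Lcn2 from 42.0 ± 4.94 to 255 ± 47.9. ER stress and integrated stress response genes rose at 5 and fell at 7 of 16 (6 and 8 adjusted over the list alone; median -0.22, 0.26 with library size alone, where 8 were higher and 4 lower, mean 0.07, camera adjusted p = 0.225). Those that fell included the ER chaperone gene Hspa5 (2029 ± 92.9 to 937 ± 40.1 CPM) and the ER stress-induced Creld2 (376 ± 58.1 to 99.5 ± 6.89), and those that rose the asparagine synthetase gene Asns (0.508 ± 0.0616 to 2.15 ± 0.272). In the progranulin and EGFR axis list 2 genes rose and 6 of 17 fell, the same adjusted over the list alone (median 0.13, a mean of 0.005 with a test direction of down, camera adjusted p = 0.609). The balance turned with library size alone, with 8 higher, 1 lower and a median of 0.63. Btc, an EGFR ligand, rose from 0.973 ± 0.295 to 2.73 ± 0.558 CPM, and Spry4, a feedback inhibitor of receptor signalling, fell from 5.94 ± 2.57 to 2.13 ± 0.349. Lysosomal genes rose at 5 and fell at 2 of 17 (the same adjusted over the list alone; median 0.02, camera adjusted p = 0.660), with the cathepsin gene Ctsb rising from 868 ± 42.7 to 1383 ± 84.0 CPM. Of the lysosomal genes 16 were higher with library size alone (median 0.52), and of the xenobiotic genes 12 were higher and 4 lower (median 0.52).

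The p53 list had 5 genes that rose and 1 that fell of 14 (the same adjusted over the list alone; median 0.25, camera adjusted p = 0.109), with Gdf15 at 3.93 ± 0.790 and 9.02 ± 0.963 CPM. Cholesterol synthesis genes rose at 2 and fell at 8 of 20 (the same adjusted over the list alone; median -0.20, 0.28 with library size alone, camera adjusted p = 0.0807). Counts of higher genes with library size alone were 13 for p53 (median 0.75) and 11 for cholesterol. Immediate-early genes rose at 6 and fell at 2 of 11 (7 and 2 adjusted over the list alone; median 0.65, camera adjusted p = 0.216), Jun rising from 8.90 ± 0.746 to 19.1 ± 0.503 CPM and Egr1 falling from 54.3 ± 8.94 to 14.2 ± 1.62. Circadian clock genes rose at 4 and fell at 4 of 13 (the same adjusted over the list alone; median -0.04, 0.43 with library size alone, where 6 were higher and 0 lower, mean 0.04, camera adjusted p = 0.867). Heat shock and hypoxia genes rose at 4 and fell at 5 of 13 (the same adjusted over the list alone; median -0.22, 0.26 with library size alone, where 6 were higher and 1 lower, mean 0.18, camera adjusted p = 0.652).

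**Figure D1:**
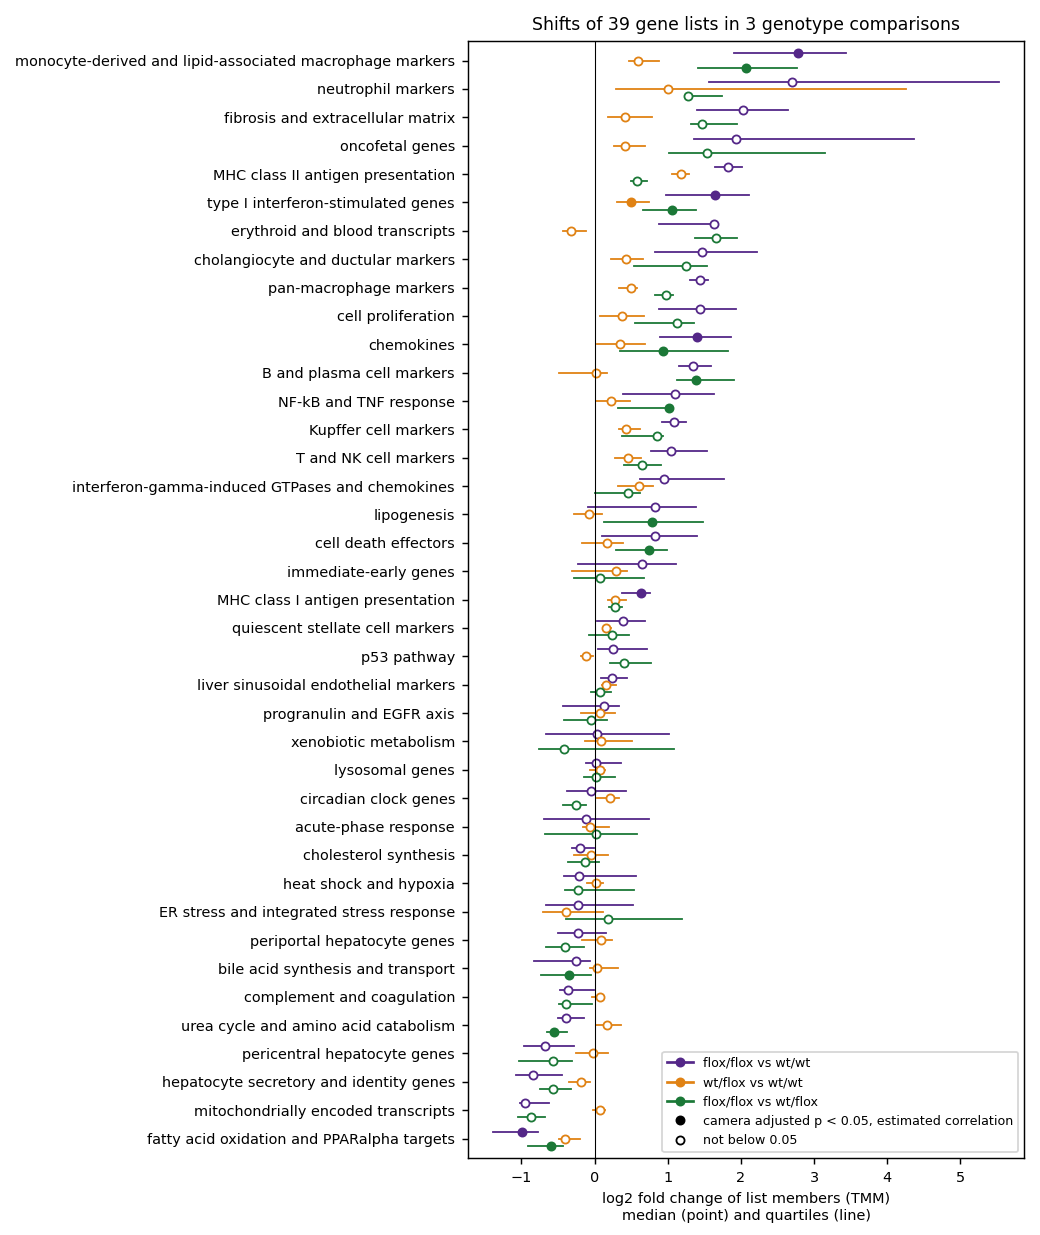
Median and quartiles of the log2 fold changes of 39 gene lists in the 3 genotype comparisons, with filled points where the camera test passed with an estimated correlation (5, 1 and 10 lists). On TMM scaling the monocyte-derived list had a median of 2.78 and the fatty acid oxidation list -0.99 in flox/flox against wt/wt.

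Over the 14034 genes tested, 7087 differed between flox/flox and wt/wt by edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment, 3775 higher and 3312 lower in flox/flox. At least 2-fold changes were found for 1886 higher and 386 lower genes, and predicted genes without an established name made up 472 of the 7087. In 8035 genes (57.3%) all 3 samples of one genotype lay above all 3 of the other, against 10% by chance. Without wt/wt replicate 3 the counts were 7988 in all, 1967 at least 2-fold higher and 390 at least 2-fold lower. With library size in place of TMM scaling, the share of higher genes among those called went from 53.3 to 93.6% (8835 higher and 605 lower), and the median gene shifted by 0.49 on the log2 scale. The log2 fold changes given here are relative to the TMM centre. Of the 39 lists, 27 passed the camera test with a preset correlation, 5 with an estimated one and 34 the fry test.

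**Figure D2:**
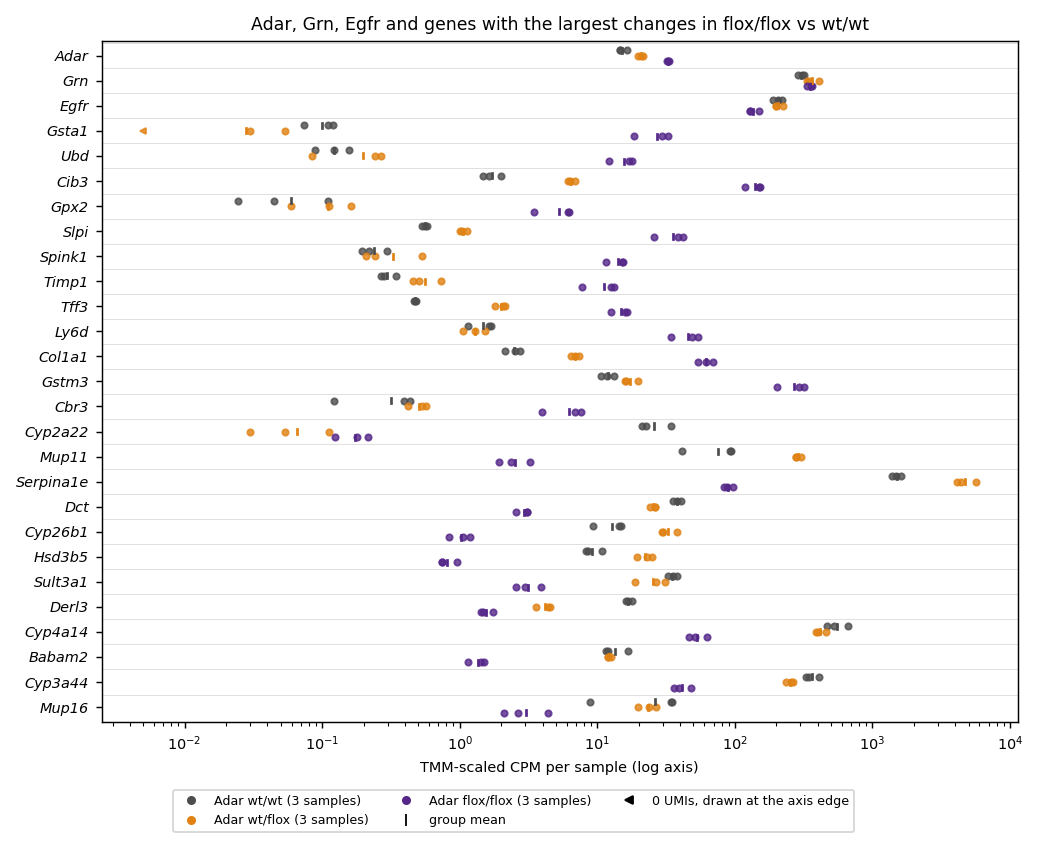
CPM per sample (3 per genotype) of Adar, Grn, Egfr and the 24 genes with the largest changes in flox/flox against wt/wt. Gsta1 went from 0.101 ± 0.0242 to 27.0 ± 7.40 CPM and Serpina1e from 1498 ± 123 to 89.5 ± 7.27.

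The comparison of wt/flox with wt/wt set 1 floxed allele against none, again without a way to tell the allele from a difference between animals. Liver-expressed genes moved both ways, by less than in flox/flox for most lists. Cyp2a22 fell from 26.0 ± 7.38 CPM to 0.0652 ± 0.0424 (7 UMIs in 3 wt/flox libraries, 1 to 4 per library, a scaled ratio of 378 with an exact interval of 183 to 941), a log2 fold change of -8.56 that was -9.17 without wt/flox replicate 2. The sulfotransferase gene Sult2a2 fell from 68.5 ± 36.6 CPM to 0.187 ± 0.0243 (20 UMIs, 6 to 8 per library, a scaled ratio of 334, 216 to 547). Sult2a1 fell from 161 ± 21.6 to 32.7 ± 2.68 CPM (log2 fold change -2.30, SE 0.12, adjusted p = 1.05e-06). Osgin1, an oxidative stress-induced growth inhibitor, fell from 255 ± 12.2 to 63.5 ± 3.12, the choline kinase gene Chka from 136 ± 8.95 to 53.6 ± 5.42, and the transcription factor gene Egr1 from 54.3 ± 8.94 to 18.1 ± 1.501. Serpina1e rose from 1498 ± 123 to 4736 ± 812 CPM (log2 fold change 1.66, SE 0.13, adjusted p = 1.82e-05), and Mup11 from 75.3 ± 29.7 to 287 ± 15.1. Cib3 rose from 1.70 ± 0.265 to 6.45 ± 0.396 CPM. The deubiquitinase gene Usp2 (2.29, SE 0.13), Noct, a rhythmically expressed phosphatase (1.56, SE 0.10), Ccn2, a connective tissue growth factor (1.75, SE 0.23), Asic5 (1.99, SE 0.12), Ugt2b38 (1.76, SE 0.16), Ptgds (1.74, SE 0.16), Adm (1.62, SE 0.21) and Pfkfb3 (1.53, SE 0.13) were also among the genes with the largest rise. Derl3 (-2.01, SE 0.11), Setdb2 (-1.84, SE 0.32), Crybb3 (-1.69, SE 0.17), Arrdc3 (-1.67, SE 0.20), Serpina9 (-1.59, SE 0.15) and Cyp3a16 (-1.54, SE 0.15) also fell. Cyp2a, Sult2a, Cyp3a, Serpina1 and Mup genes belong to families of near-identical copies, so reads could be split between members, and the same holds for the Gsta, Gstm, H2-Q and immunoglobulin genes.

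Type I interferon-stimulated genes rose at 20 of 39 in wt/flox against wt/wt, and at 28 when adjusted over the list alone, with Ifit1 at 8.19 ± 1.24 and 21.9 ± 2.91 CPM. The interferon-stimulated gene median was 0.50 (camera adjusted p = 1.04e-13, adjusted p = 0.00342 with an estimated correlation). The interferon-gamma-induced list rose at 11 of 18 (13 adjusted over the list alone), and MHC class I genes at 8 of 19 (9 adjusted over the list alone). The interferon-gamma list median was 0.61 (camera adjusted p = 2.74e-07, adjusted p = 0.0786 with an estimated correlation). The class I median was 0.28 (camera adjusted p = 2.71e-05, adjusted p = 0.0524 with an estimated correlation). All 7 MHC class II genes rose (7 adjusted over the list alone), H2-Ab1 from 38.99 ± 1.64 to 100.76 ± 7.71 CPM. The class II median was 1.18 (camera adjusted p = 5.32e-09, adjusted p = 0.103 with an estimated correlation). Kupffer cell markers rose at 8 of 9 (8 adjusted over the list alone), with the scavenger receptor gene Marco at 19.6 ± 3.10 and 32.6 ± 5.17 CPM, and pan-macrophage markers at 8 of 15 (14 adjusted over the list alone), with the complement gene C1qb at 92.8 ± 4.82 and 154 ± 18.9. The Kupffer cell median was 0.42 (camera adjusted p = 1.46e-05, adjusted p = 0.116 with an estimated correlation). The pan-macrophage median was 0.50 (camera adjusted p = 1.54e-07, adjusted p = 0.140 with an estimated correlation). Monocyte-derived and lipid-associated markers rose at 6 of 16 (13 adjusted over the list alone), and T and NK cell markers at 3 of 16 (3 adjusted over the list alone). The monocyte-derived median was 0.59 (camera adjusted p = 2.74e-07, adjusted p = 0.0786 with an estimated correlation). The T and NK median was 0.46 (camera adjusted p = 9.11e-05, adjusted p = 0.103 with an estimated correlation). Chemokines rose at 6 of 18 (6 adjusted over the list alone), and matrix genes at 10 of 24 (14 adjusted over the list alone), Col1a1 from 2.46 ± 0.314 to 6.90 ± 0.449 CPM. The chemokine median was 0.35 (camera adjusted p = 0.00405, adjusted p = 0.0786 with an estimated correlation). The matrix gene median was 0.42 (camera adjusted p = 6.07e-07, adjusted p = 0.290 with an estimated correlation). Oncofetal genes rose at 4 of 12 (5 adjusted over the list alone), proliferation genes at 3 of 23 (3 adjusted over the list alone), and ductular markers at 3 of 11 with 1 falling (4 and 1 adjusted over the list alone). The oncofetal median was 0.42 (camera adjusted p = 0.00204, adjusted p = 0.253 with an estimated correlation), and it was 0.67 without wt/wt replicate 1. The proliferation median was 0.38 (camera adjusted p = 0.00400, adjusted p = 0.313 with an estimated correlation). The ductular median was 0.43 (camera adjusted p = 0.0195, adjusted p = 0.341 with an estimated correlation), and without wt/wt replicate 2 it was 0.33 and did not pass (adjusted p = 0.0688, with 0.0086 to 0.341 over 12 alternatives). Sinusoidal endothelial markers rose at 2 of 12 (2 adjusted over the list alone), with Lyve1 at 4.95 ± 0.879 and 10.8 ± 1.21 CPM, and the stellate cell list shifted by a median of 0.15 (camera adjusted p = 0.0496, adjusted p = 0.317 with an estimated correlation) without a member that passed by itself. The stellate shift did not pass without wt/wt replicate 1, 2 or 3 (medians 0.21, 0.19 and 0.20), wt/flox replicate 1 or 2 (0.18 and 0.15) or flox/flox replicate 2 (0.15). The endothelial median was 0.16 (camera adjusted p = 0.0155, adjusted p = 0.232 with an estimated correlation).

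Fatty acid oxidation and PPARalpha target genes fell in wt/flox at 13 of 24 (15 fell and 1 rose adjusted over the list alone), among them the pantetheinase gene Vnn1 (121 ± 9.72 to 72.9 ± 4.34 CPM), the nuclear receptor gene Ppara (7.90 ± 0.370 to 4.67 ± 0.751) and Fabp1 (7662 ± 972 to 4572 ± 146). The fatty acid oxidation median was -0.40 (camera adjusted p = 2.12e-08, adjusted p = 0.0786 with an estimated correlation). ER stress and integrated stress response genes fell at 8 of 16 (9 adjusted over the list alone), Creld2 from 376 ± 58.1 to 166 ± 8.11 CPM and Hspa5 from 2029 ± 92.9 to 1245 ± 83.3. The ER stress median was -0.39 (camera adjusted p = 5.02e-04, adjusted p = 0.0786 with an estimated correlation). Secretory and identity genes fell at 2 of 18, and at 7 adjusted over the list alone, with the transthyretin gene Ttr at 18023 ± 1587 and 12778 ± 846 CPM. The secretory gene median was -0.18 (camera adjusted p = 6.98e-04, adjusted p = 0.290 with an estimated correlation). Urea cycle and amino acid genes rose at 5 and fell at 1 of 18 (7 and 1 adjusted over the list alone), the glycine methyltransferase gene Gnmt rising from 2180.1 ± 171 to 3429 ± 442 CPM. The urea cycle median was 0.16 (camera adjusted p = 0.0155, adjusted p = 0.179 with an estimated correlation). Lists that did not pass the camera test still held genes that passed by themselves, including Slco1a1 (86.6 ± 2.51 to 166 ± 7.70 CPM), the xenobiotic-inducible Cyp2b10 (16.4 ± 0.989 to 32.3 ± 4.29), and the lysophospholipid transporter gene Mfsd2a (110.3 ± 0.969 to 239 ± 28.8). The lipogenic transcription factor gene Srebf1 fell from 64.2 ± 6.93 to 36.7 ± 3.86 CPM, in a list with 2 genes higher and 2 lower of 15. The clock genes Ciart (1.69, SE 0.22) and Per1 (0.56, SE 0.09) rose, in a list with 3 higher and 1 lower of 13. On library size alone 13 pan-macrophage and 11 monocyte-derived markers were higher, and 10 fatty acid oxidation genes lower with 1 higher. On that scaling the medians of the p53, acute-phase, pericentral, lipogenesis and cholesterol lists turned from -0.12, -0.06, -0.02, -0.08 and -0.04 to 0.00, 0.05, 0.09, 0.03 and 0.07. Mean and median differed in sign for B and plasma cell markers (mean -0.16, median 0.02) and acute-phase genes (mean 0.04). Of 39 lists, 19 passed with the preset correlation, 1, the type I interferon list, with an estimated one and 26 by fry.

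edgeR's test called 1662 genes between wt/flox and wt/wt, 879 higher and 783 lower in wt/flox, with 166 at least 2-fold higher, 86 at least 2-fold lower and 94 predicted genes among the 1662. The genotypes did not overlap in 4700 genes (33.5%, against 10% by chance). Without wt/flox replicate 1, 2 or 3 the count was 1058, 739 or 871. Without wt/wt replicate 3 it was 2483 (208 and 90 at least 2-fold higher and lower), with only these 6 samples in the fit 1000, and with the number in the file names as a block 2994. With library size alone the share of higher genes went from 52.9 to 78.8% (1405 higher and 377 lower), with the median gene shifting by 0.11 on the log2 scale.

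The comparison of flox/flox with wt/flox set 2 floxed alleles against 1, with the same limit on animals. Several genes were high in wt/flox and low in flox/flox: Mup11 was at 287 ± 15.1 CPM in wt/flox and 2.51 ± 0.676 in flox/flox, and Serpina1e at 4736 ± 812 and 89.5 ± 7.27 (log2 fold change -5.73, SE 0.16, adjusted p = 6.43e-10). Slco1a1 was at 166 ± 7.70 and 12.4 ± 1.51 CPM and Cyp17a1, a steroid hydroxylase, at 189.5 ± 10.97 and 18.6 ± 2.29. Sult2a2, near 0 in wt/flox, was at 43.2 ± 7.37 CPM in flox/flox, a scaled ratio of 229.9 (exact interval 149 to 377). Gsta1 had 3 UMIs over the wt/flox libraries and 3097 over the flox/flox ones, a scaled ratio of 950 (exact interval 325 to 4610) and a log2 fold change of 9.76, which was 10.61 without wt/flox replicate 1. Slpi (5.06, SE 0.19), Ubd (6.30, SE 0.26), Spink1 (5.41, SE 0.24), Ly6d (5.15, SE 0.21), Gpx2 (5.51, SE 0.37), Cib3 (4.44, SE 0.13), Timp1 (4.30, SE 0.25), Gstm3 (3.97, SE 0.17), the immunoglobulin gene Iglc1 (3.83, SE 0.65) and the sphingomyelinase gene Smpd3 (3.80, SE 0.21) rose. Iglc1 varied between samples (8.73 ± 7.14 CPM in flox/flox), with a log2 fold change of 2.93 without flox/flox replicate 2 and 4.75 without wt/flox replicate 1. Cyp26b1 (-4.97, SE 0.21), Hsd3b5 (-4.79, SE 0.17), Sult5a1 (-3.31, SE 0.11), Mup7 (-3.44, SE 0.51), Mup1 (-3.17, SE 0.35), Babam2 (-3.15, SE 0.17), Dct (-3.13, SE 0.11) and Ugt2b38 (-3.13, SE 0.19) fell.

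Type I interferon-stimulated genes rose from wt/flox to flox/flox at 36 of 39 (37 adjusted over the list alone), with Irf7 at 38.3 ± 0.797 and 151 ± 14.6 CPM. The interferon-stimulated gene median was 1.06 (camera adjusted p = 1.19e-14, adjusted p = 0.00301 with an estimated correlation). All 16 monocyte-derived and lipid-associated markers rose (16 adjusted over the list alone), with Trem2, a lipid-sensing receptor, at 0.916 ± 0.172 and 6.20 ± 1.16 CPM, as did all 15 pan-macrophage markers (15 adjusted over the list alone). The monocyte-derived median was 2.06 (camera adjusted p = 1.08e-09, adjusted p = 0.0365 with an estimated correlation). The pan-macrophage median was 0.97 (camera adjusted p = 1.28e-07, adjusted p = 0.0948 with an estimated correlation). Matrix genes rose at 23 of 24 (23 adjusted over the list alone), and B and plasma cell markers at 9 of 10 (9 adjusted over the list alone). The matrix gene median was 1.47 (camera adjusted p = 1.19e-14, adjusted p = 0.0948 with an estimated correlation). The B cell median was 1.38 (camera adjusted p = 8.99e-05, adjusted p = 0.0365 with an estimated correlation). Erythroid and blood transcripts rose at 6 of 7 (6 adjusted over the list alone). Their median was 1.66 (camera adjusted p = 0.00816, adjusted p = 0.362 with an estimated correlation), and blood left in the sections was not tested here either. Lipogenesis genes rose at 10 of 15 and fell at 1 (the same adjusted over the list alone), with Scd1 at 1679 ± 103 and 5549 ± 468 CPM. The lipogenesis median was 0.79 (camera adjusted p = 1.11e-04, adjusted p = 0.0365 with an estimated correlation). Cell death effectors rose at 9 of 15 and fell at 1 (12 and 1 adjusted over the list alone), NF-kB genes rose at 10 of 14 (11 adjusted over the list alone), and chemokines rose at 12 and fell at 2 of 18 (14 and 2 adjusted over the list alone). The cell death median was 0.74 (camera adjusted p = 6.74e-04, adjusted p = 0.0417 with an estimated correlation). The NF-kB median was 1.01 (camera adjusted p = 1.10e-04, adjusted p = 0.0417 with an estimated correlation). The chemokine median was 0.93 (camera adjusted p = 0.00137, adjusted p = 0.0423 with an estimated correlation). Fatty acid oxidation genes fell at 20 of 24 (20 adjusted over the list alone), Cyp4a10 from 383 ± 25.5 to 54.5 ± 9.17 CPM, and urea cycle genes at 13 of 18 (15 adjusted over the list alone). The fatty acid oxidation median was -0.59 (camera adjusted p = 3.39e-11, adjusted p = 0.0378 with an estimated correlation). The urea cycle median was -0.55 (camera adjusted p = 3.09e-07, adjusted p = 0.0365 with an estimated correlation). Bile acid genes fell at 10 and rose at 2 of 18 (the same adjusted over the list alone). The bile acid median was -0.35 (camera adjusted p = 1.99e-04, adjusted p = 0.0378 with an estimated correlation). With library size alone 12 fatty acid oxidation genes were lower and 2 higher (median -0.21), 5 urea cycle genes lower (median -0.18), and 7 bile acid genes lower and 6 higher. On that scaling the medians of the bile acid, progranulin and EGFR, cholesterol, clock and heat shock lists turned from -0.35, -0.05, -0.13, -0.25 and -0.22 to 0.03, 0.33, 0.25, 0.13 and 0.15. Mean and median differed in sign for xenobiotic genes (mean 0.51, median -0.41, passed by fry in the direction up) and heat shock genes (mean 0.02). Of 39 lists, 29 passed with the preset correlation, 10 with an estimated one and 34 by fry.

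edgeR's test called 5356 genes between flox/flox and wt/flox, 3045 higher and 2311 lower in flox/flox, with 1258 at least 2-fold higher, 308 at least 2-fold lower and 351 predicted genes. The genotypes did not overlap in 7807 genes (55.6%, against 10% by chance). Without wt/wt replicate 3 in the fit the counts were 7121, 1341 and 336. With library size alone the share of higher genes went from 56.9 to 92.9% (7627 higher and 581 lower), with the median gene shifting by 0.38.

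Across the 3 genotypes together, 7315 of 14034 genes (52.1%) differed by edgeR's quasi-likelihood F-test, and 8796 did without wt/wt replicate 3. Among the 7087 genes called in flox/flox against wt/wt, wt/flox log2 fold changes had a slope of 0.243 on the flox/flox ones and the same sign in 79.9%, a comparison across genes, which are not independent replicates. Both comparisons share the wt/wt libraries, so simulated groups with no effect gave a slope of 0.452 and the same sign in 65.5%. The simulated flox/flox changes held only noise, so this slope and this share of signs cannot be set against the observed ones. The covariance was 0.333 against 0.0152 ± 0.0007 (SD over 20 simulations), a difference of 0.318. Genes were simulated independently, so a deviation of a wt/wt library shared by many genes was left out. Genes called higher in both comparisons numbered 649, against 236 for independent lists, those lower in both 530 against 185, and those called in opposite directions 49 against 211 and 54 against 207. The 3 wt/wt libraries are too few to split, so part of the excess may come from the shared controls.

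Position along the portal-to-central axis of the liver lobule was taken from expression, since no spot coordinates were used here. In each sample the tertile of spots with the most pericentral transcripts was compared with the tertile with the most periportal ones. Several enzyme transcripts changed their place on this expression index in flox/flox. The pericentral and periportal anchors parted spots less there (Spearman's rho over spots -0.70 to -0.59, against -0.89 to -0.82 in wt/wt). Whether the index tracks the same axis in flox/flox was not tested. Gstm3 was at 26.6 CPM in central and 3.68 CPM in portal spots of wt/wt and at 183 and 368 CPM in flox/flox, so its central-minus-portal log2 difference went from 2.81 to -0.998 (interaction -3.81, SE 0.12, edgeR adjusted p = 6.0e-34). Cyp2a5, a coumarin hydroxylase, went from 3.26 to 0.42 (262 and 26.8 CPM in wt/wt, 315 and 239 in flox/flox, interaction -2.84, SE 0.08). Gstm1 went from 1.14 to -0.64 (-1.78, SE 0.04), Gstm2 from 2.38 to 0.58 (-1.81, SE 0.08), Cyp2d9 from 2.51 to 0.87 (-1.63, SE 0.09) and the retinaldehyde dehydrogenase gene Aldh1a1 from 1.252 to 0.23 (-1.02, SE 0.05). In the other direction Hao2, a peroxisomal hydroxyacid oxidase, went from -1.40 to 1.00 (20.6 and 54.7 CPM in wt/wt, 20.9 and 10.5 in flox/flox, interaction 2.40, SE 0.10). Serpina1e went from -0.94 to 0.36 (1.29, SE 0.07), Cyp2c40 from -0.42 to 0.59 (1.01, SE 0.05), Fabp1 from -0.15 to 0.68 (0.83, SE 0.04), Apoa4 from -1.19 to -0.20 (0.99, SE 0.06) and Cyp2c69 from 0.59 to 1.87 (1.28, SE 0.06). In wt/flox the same 12 genes lay within 0.54 of wt/wt, with Hao2 at -1.86, Serpina1e at -0.40 and Gstm3 at 2.54. Of these, Serpina1e (interaction 0.54, edgeR adjusted p = 3.96e-11), Fabp1 (0.26, 4.16e-06), Cyp2c40 (0.25, 6.66e-04) and Hao2 (-0.46, 0.00298) passed in wt/flox against wt/wt and the others did not. Hao2 thus moved opposite to its change in flox/flox. Of the pericentral list, 10 of 16 tested genes became more portal and 2 more central in flox/flox (median difference 1.75 in wt/wt, 1.47 in flox/flox), and of the periportal list 12 of 13 became more central (-0.81 to -0.35). Mitochondrially encoded transcripts became more central at 12 of 13 members, urea cycle genes at 11 of 18 with 1 more portal, and xenobiotic genes more portal at 11 and more central at 3 of 24.

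The edgeR interaction test, with the sample as a block, called 1245 of 13053 genes in flox/flox against wt/wt, 773 more central and 472 more portal. It called 114 in wt/flox against wt/wt (50 and 64) and 870 in flox/flox against wt/flox (547 and 323). Without wt/wt replicate 3 these counts were 1076, 90 and 939, and the 114 became 67 without wt/flox replicate 1 and 59 without replicate 2. Central spots held fewer UMIs than portal ones, and with spots thinned to 3000 UMIs the counts were 481, 50 and 363. Genes with a zone difference numbered 4857 in wt/wt, 3754 in wt/flox and 3263 in flox/flox, a fall lower depth may give. The slope of differences on wt/wt over 1346 genes was 0.884 (SE over genes 0.0105) in wt/flox and 0.586 (0.0115) in flox/flox. Interferon-stimulated genes rose in flox/flox against wt/wt in both regions, at 39 of 39 central (median log2 fold change 1.80) and 38 of 39 portal (1.69), and so did all 15 pan-macrophage markers (1.55 and 1.43) and 23 of 24 matrix genes in each (2.07 and 1.90). Fatty acid oxidation genes fell at 22 of 24 in each region, and urea cycle genes at 4 of 18 in central and 13 of 18 in portal spots.

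**Figure D3:**
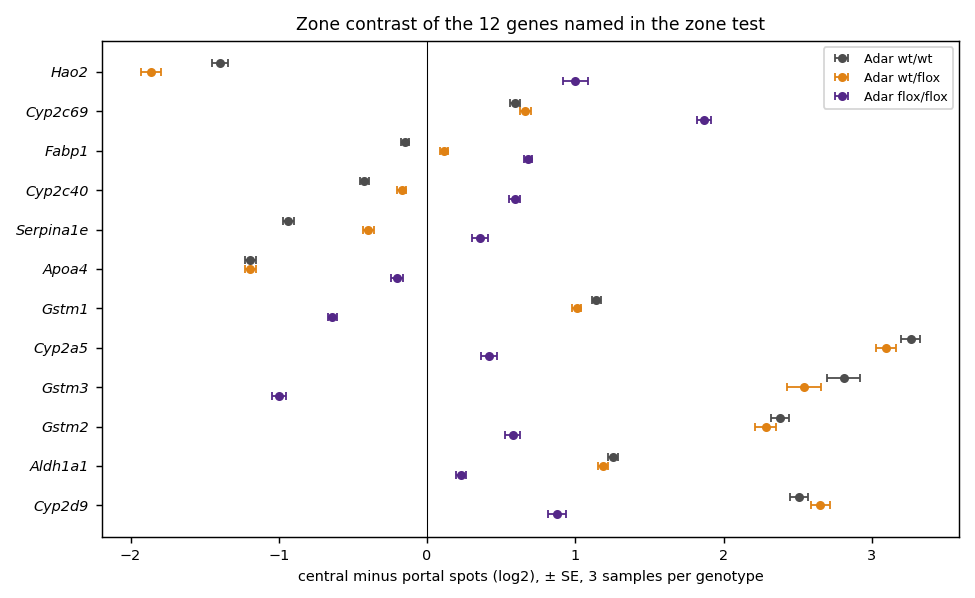
Central-minus-portal log2 difference (± SE, 3 samples per genotype) of the 12 genes named for the zone test. Gstm3 went from 2.81 in wt/wt to -0.998 in flox/flox and Hao2 from -1.40 to 1.00.

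The spread of transcripts between spots was compared after thinning each spot to 3000 UMIs, with 1 value per sample and exact permutation tests over the 280 splits of 9 samples, adjusted over 6 measures. Matrix transcripts in flox/flox had a variance-to-mean ratio over spots of 4.86 ± 0.325 against 1.20 ± 0.153 in wt/wt and 1.44 ± 0.126 in wt/flox (n = 3, adjusted exact p = 0.0214). Pan-macrophage transcripts had ratios of 2.04 ± 0.143, 1.24 ± 0.0595 and 1.30 ± 0.0538 in flox/flox, wt/wt and wt/flox (adjusted exact p = 0.0214). For interferon-stimulated genes the ratios were 1.48 ± 0.217, 1.26 ± 0.117 and 1.65 ± 0.115, and for T and NK cell markers 1.18 ± 0.0786, 1.08 ± 0.0231 and 1.07 ± 0.0722, and neither difference passed (adjusted exact p = 0.107 for both). Spearman's rho over spots of macrophage transcripts with Grn was 0.0882 ± 0.0278 in flox/flox, against 0.0083 ± 0.0053 in wt/wt and 0.0242 ± 0.0166 in wt/flox (adjusted exact p = 0.0214). The rho of macrophage with interferon-stimulated transcripts was 0.103 ± 0.0017 in flox/flox, 0.0246 ± 0.0186 in wt/wt and 0.0428 ± 0.0291 in wt/flox (adjusted exact p = 0.0268). In flox/flox the rho was 0.0627 for Grn and 0.0681 for interferon-stimulated genes with 1500 UMIs, and 0.117 and 0.136 with 5000, so it depends on the counts, and macrophage transcripts were more abundant in flox/flox. A difference in rho is therefore not free of a difference in level, and a variance-to-mean ratio grows with the mean level. A measure relative to the mean, the squared coefficient of variation beyond counting error, was therefore added after the data were seen, with p values not adjusted over measures. For matrix transcripts it was 0.469 in wt/wt, 0.648 in wt/flox and 1.36 in flox/flox (exact p = 0.0143 over the 3 genotypes, 0.0250 with spots thinned to 5000 UMIs and 0.229 with 1500), so the difference was not past the threshold at each depth. For interferon-stimulated genes it was 0.117, 0.203 and 0.0632 (exact p = 0.0107 over the 3 genotypes, 0.0286 with 5000 UMIs and 0.0357 with 1500), and flox/flox against wt/wt alone had an exact p of 0.2. For macrophage transcripts it was 0.164, 0.133 and 0.195 (exact p = 0.104, 0.0393 with 5000 UMIs and 0.118 with 1500). Exact tests of 3 samples against 3 cannot go below p = 0.1, and the smallest p over all 9 samples is 0.00357.

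**Figure D4:**
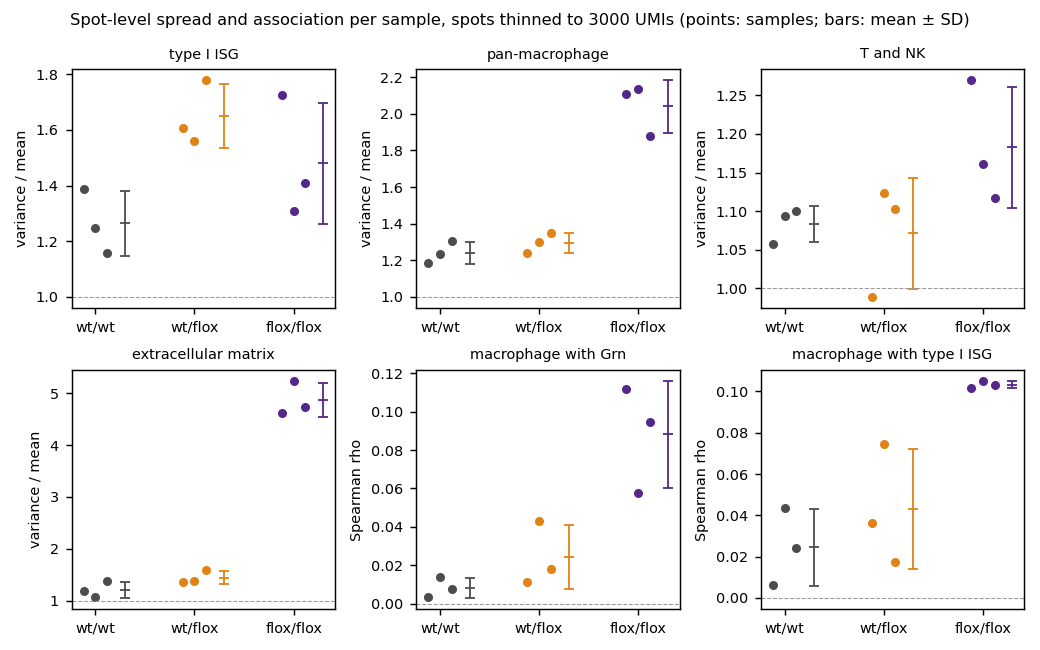
Spread over spots and association with macrophage transcripts per sample (points) with mean ± SD of 3 samples, on spots thinned to 3000 UMIs. The variance-to-mean ratio of matrix transcripts was 4.86 ± 0.325 in flox/flox and 1.20 ± 0.153 in wt/wt.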

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

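The tests of a lower hepatocyte share, of noise in the zone assignment, of paralogs and of a difference between animals were chosen after the results were seen, as was the count of lists with an estimated correlation in other splits. The genotypes differed in the zone contrast of many genes by the test of the difference: 1245 in flox/flox against wt/wt, 114 in wt/flox against wt/wt (67 without wt/flox replicate 1 and 59 without replicate 2) and 870 in flox/flox against wt/flox. The named genes among them became more central by 2.40 (Hao2), 1.28 (Cyp2c69), 0.83 (Fabp1), 1.01 (Cyp2c40), 1.29 (Serpina1e) and 0.99 (Apoa4) on the log2 scale, or more portal, with -1.78 (Gstm1), -2.84 (Cyp2a5), -3.81 (Gstm3), -1.81 (Gstm2), -1.02 (Aldh1a1) and -1.63 (Cyp2d9).

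Zonation was weaker in flox/flox, with a slope of 0.586 on wt/wt. Lower depth per spot was argued against as the whole cause, since with spots thinned to 3000 UMIs the slope over 803 genes was 0.457 (SE over genes 0.0137), below the 0.781 (0.0136) of wt/flox over the same genes by more than the limit of 0.05 set beforehand. A noisier zone assignment or blurred transcripts stays open for the slope, and may account for it: 4.98% of the 2369 genes zonated in both genotypes had opposite signs, and pericentral and periportal anchors parted spots less in flox/flox (Spearman's rho over spots -0.70 to -0.59, against -0.89 to -0.82 in wt/wt), where anchors such as Oat (-1.24), Slc1a2 (-1.13), Hsd17b6 (-1.32) and Gls2 (-0.91) fell against wt/wt (log2 fold change). Of 1155 genes zonated in both genotypes at an adjusted p below 0.001, 3.9% were opposite (interval 2.86 to 5.18%), against a limit of 0.1%. That limit was set after the 4.98% had met a looser one, and the interval treats genes as independent. For the genes that turned sign, this share argues only weakly against noise alone. An index that tracks another axis in flox/flox, and an effect of the genotype itself, remain open and were not tested.

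Markers of non-hepatocyte cells were higher in flox/flox. A lower share of hepatocyte RNA alone was argued against, since the monocyte-derived and sinusoidal endothelial list medians differed by 2.54 on the log2 scale, where such a share would raise both alike. These were the highest and lowest marker medians, picked after they were seen. Between them, pan-macrophage quartiles (1.30 to 1.55) overlapped those of B cell markers (1.15 to 1.59) but not those of stellate cell markers (0.0317 to 0.695). With all libraries thinned to the same total the pan-macrophage median was 1.39. Thinning summed counts at random keeps the share of each gene on average, so this value could hardly move. It therefore decides nothing about depth, and the lower depth per spot in flox/flox was not tested for these markers. More cells of some types, higher transcription per cell, and a lower hepatocyte share beside either of these stay open, as does the genotype as their origin. Blood left in the sections was not tested and stays open for the leukocyte markers, since 6 of 7 erythroid and blood transcripts rose as well (median 1.63).

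Sult2a2 was near 0 in all wt/flox samples, and Cyp2a22 in all wt/flox and flox/flox samples. The summed Sult2a level in wt/flox was 0.625 of that in wt/wt (371 ± 39.6 and 594 ± 59.7 CPM), and no other member was higher in wt/flox. Sult2a1 fell as well (161 ± 21.6 to 32.7 ± 2.68 CPM), so the sum would fall even if Sult2a2 reads had moved to a paralog. For Sult2a2 a move of reads to a paralog therefore cannot be told apart by the sum. Nor can such a move be told apart for Cyp2a22, since the summed Cyp2a level was 0.832 of wt/wt and the 26.0 CPM of Cyp2a22 lie below the SD of that sum (102 CPM). A difference between animals that the sections of a genotype share cannot be told apart from the floxed alleles either, since all 3 wt/flox samples were low (mean Sult2a2 0.187 CPM) and nothing ties samples to animals.

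Of 100 splits drawn from the 280 of the 9 samples into 3 groups of 3, only 1, the real one, called as many genes (7315, the highest other 5344). If the samples of a genotype are sections of 1 tissue, the real split would stand out under any difference between animals. The splits therefore cannot tell the genotype from such a difference. The 10 splits of 6 samples are too few for a share below 0.1: for each comparison 1 split, the real one, gave as many genes. In flox/flox against wt/wt the real split called 7087 genes (1886 and 386 at least 2-fold higher and lower), in wt/flox against wt/wt 1662 (166 and 86) and in flox/flox against wt/flox 5356 (1258 and 308), and the highest other split called 0 in each by edgeR, with 1784, 1398 and 300 genes at an unadjusted p below 0.05 against 7877, 3941 and 6617. Lists numbered 27, 19 and 29, with 26, 13 and 22 in the highest other split. With an estimated correlation in limma the other splits gave 0 lists against 5, 1 and 10. Other splits of 6 samples still hold unequal numbers of each genotype, so they are not free of a genotype difference. They also mix genotypes within a group, which widens the spread there, so low counts could be expected in them beforehand. Their low counts of genes, here and in the zone test below, and of lists with an estimated correlation therefore do not support the real ones. For the zone test the highest other splits gave 0, 7 and 0 genes (edgeR, 624, 712 and 653 at an unadjusted p below 0.05) against 1245, 114 and 870 (2568, 1141 and 2164).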

How the results depend on the processing

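Each of 486 gene results was recomputed under the alternatives: direction and side of the threshold were kept 10343 times, and 219 values (64 results) were weaker, 6 (2 results) stronger and 8 (5 results) reversed. All 12 zone genes kept both 144 of 144 times, and the 75 list results were the same 825 times and weaker 75 times (59 results), with no reversal. These 59 list results were the ones that did not pass camera with an estimated correlation. Most other settings for lists only left out a sample. With a mean of at least 5 CPM, which tests fewer genes, counts were 3646 (482 and 144 at least 2-fold higher and lower) in flox/flox against wt/wt, 49 and 26 at least 2-fold in wt/flox against wt/wt, 2909 (304 and 102) in flox/flox against wt/flox, and 3892 over 3 genotypes. With library size alone, which moves the centre, they were 3226 and 139 at least 2-fold in flox/flox against wt/wt, 250 at least 2-fold higher in wt/flox against wt/wt, and 8208 (2359 and 164) in flox/flox against wt/flox. For wt/flox against wt/wt the file-name block gave 2994, the 2 genotypes alone 1000, and samples left out 739 to 2483 (739 without wt/flox replicate 2, 871 without replicate 3, 1058 without replicate 1, 2483 without wt/wt replicate 3); the cause was not tested. An estimated correlation gave 5, 1 and 10 lists. Zone counts with spots thinned were 481, 50 and 363, and samples left out gave 59 to 132 in wt/flox against wt/wt (67 without wt/flox replicate 1, 59 without replicate 2). The squared coefficient of variation, chosen after seeing the data, turned the flox/flox minus wt/wt difference in spread to -0.0539 for interferon-stimulated genes and -0.5645 for T and NK markers, and gave 0.031 for macrophages, and it divides by the mean. The agreement slope was 0.167 over genes called in flox/flox against wt/flox and 0.214 to 0.271 with samples left out. Reversed genes were Grn in flox/flox against wt/flox (0.33 with library size alone, 0.0425 with at least 5 CPM, and -0.107 to 0.0432 with samples left out, the ends without wt/flox replicates 3 and 2), Erbb3 (0.0133), Lamp2 (0.014) and Otc (0.0076) in flox/flox against wt/wt with library size alone, and Egfr in wt/flox against wt/wt (-0.0545 to 0.066 with samples left out, -0.0545 without wt/flox replicate 2, -0.0511 without wt/wt replicate 3 and 0.066 without wt/wt replicate 2); the cause was not tested. For replicate numbers shared with flox/flox samples r was mixed (0.282, -0.118 and 0.343 with wt/wt, 0.015, -0.015 and 0.181 with wt/flox). With unlike numbers it reached 0.350, for wt/wt replicate 2 with flox/flox replicate 1, so a pairing was neither shown nor excluded. The replicate block gave 7664, 2462 and 6128 genes. Of 486 gene and 75 list results it changed 1, Grn in flox/flox against wt/wt (edgeR adjusted p = 0.0440, range over alternatives 9.1e-05 to 0.230). The file-name block called Grn in flox/flox against wt/wt (adjusted p = 0.0425, the same range) and in wt/flox against wt/wt (0.0419, range 0.0352 to 0.365).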

Other observations

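The test of NRF2 targets used a list written after the genotype comparisons were seen, and the association of Egfr with macrophage transcripts was also chosen after the other results were seen. From wt/flox to flox/flox, p53 pathway genes rose at 8 of 14 and fell at 1 (9 and 1 adjusted over the list alone), Phlda3, a p53-induced inhibitor of AKT, from 1.65 ± 0.337 to 6.31 ± 0.930 CPM and the stress cytokine gene Gdf15 from 4.20 ± 0.463 to 9.02 ± 0.963. The p53 list median was 0.40 (camera adjusted p = 0.00806, adjusted p = 0.0794 with an estimated correlation). Ductular markers rose at 9 of 11 (9 adjusted over the list alone), Prom1 from 6.04 ± 0.576 to 17.8 ± 1.72 CPM, and Kupffer cell markers at 7 of 9 (7 adjusted over the list alone), with the scavenger receptor-like Cd5l at 127 ± 8.57 and 249 ± 13.01. The ductular median was 1.2503 (camera adjusted p = 1.84e-04, adjusted p = 0.133 with an estimated correlation). The Kupffer cell median was 0.85 (camera adjusted p = 5.98e-04, adjusted p = 0.133 with an estimated correlation). Pericentral genes fell at 16 of 22 and rose at 2 (the same adjusted over the list alone), the glutamate transporter gene Slc1a2 from 66.2 ± 7.78 to 27.0 ± 1.71 CPM, and mitochondrially encoded transcripts fell at 12 of 13 (13 adjusted over the list alone). With library size alone 11 pericentral genes were lower and 3 higher, 9 mitochondrial transcripts lower, and 12 p53 genes higher. The pericentral median was -0.57 (camera adjusted p = 1.76e-06, adjusted p = 0.0948 with an estimated correlation). The mitochondrial median was -0.87 (camera adjusted p = 7.60e-07, adjusted p = 0.178 with an estimated correlation).

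Over spots thinned to 3000 UMIs, Egfr and macrophage transcripts had a Spearman rho of -0.0581 ± 0.0066 in flox/flox, -0.0096 in wt/wt and -0.0095 in wt/flox (n = 3, exact p = 0.0357 over the 280 splits of 9 samples). With 1500 and 5000 UMIs the flox/flox value was -0.0332 and -0.0611, and the difference in rho is not free of the higher macrophage level in flox/flox.

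Gsta1, Gsta2, Gstm3, Gpx2 and Cbr3 rose in flox/flox, and a candidate explanation is activity of NRF2, which induces such genes. Of 16 other NRF2 targets tested, 7 rose and 4 fell in flox/flox against wt/wt, with a median of 0.07 (camera p = 0.244, p = 0.368 with an estimated correlation). Members that go both ways decide nothing about NRF2, so the bound set for its absence was not a fair one and it cannot be told apart from other inducers. In flox/flox against wt/flox 6 rose and 2 fell (camera p = 0.0359, p = 0.131 with an estimated correlation).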
